A study of Arabidopsis thaliana with 56 samples.

How the data were processed

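Polysome-bound RNA was measured in 56 libraries from roots of Arabidopsis seedlings 9 to 11 days old at inoculation, sequenced on an Illumina Genome Analyzer IIx. Each library came from 1 of 4 cell layers, marked by the promoter that drove the tagged ribosomal protein, from 1 of 3 microbe experiments, and from infected or mock-treated plants. Mock plants received the diluted Murashige and Skoog solution in water without microbes. Groups were taken from the labels, giving 24 groups, 16 of 2 libraries and 8 of 3. The labels spell the oomycete's genus Phytophtora and the titles use the older genus name Piriformospora for Serendipita indica.

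The authors deposited 1 Salmon table per library, and per the submitters' processing notes Salmon 0.7.2, R 3.5.1 and DESeq2 were used, with no role stated for the last 2. The transcript set, genome build and filters are not given in the sources used here. The deposited estimated counts (expected counts, the reads Salmon assigns to each transcript, which need not be whole) are not normalized. The deposited values named TPM, per the file headers, are abundances corrected for effective transcript length and scaled to the same sum in each library, and the deposited effective length is another column of the same tables. Estimated counts of 41392 transcripts were summed to 33326 genes by their locus code and rounded to whole numbers. Of these genes 32570 were found by locus code in the TAIR10.1 annotation, which was used for symbols, gene classes and the 125 chloroplast and 143 mitochondrial genes and not for positions. Salmon shares reads between similar transcripts by estimation, so levels of near-identical paralogs and pseudogenes are uncertain, as are those of overlapping and antisense genes, since strand handling is not given in the sources used here. CPM values were computed from the rounded counts and each library's total count.

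Tests used edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest) with TMM scaling in R 4.3.3, after filterByExpr by group, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Each experiment was fitted over its 8 groups, with contrasts of infected against mock in each layer, their mean over the 4 layers, and an F-test of differences between the 4 layer effects. A fit over the 56 libraries gave the differences between mean responses of microbes and the contrast of each mock layer with the other 3. The standard error printed beside a log2 fold change is its size divided by the square root of F, and is approximate. Where all libraries of a group held 0 counts, folds were bounded with a floor of 3 counts over the group, and list medians were also computed with such members at their bound. Floors cover counting error only.

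The 28 gene lists, with 412 genes, the tests, the alternatives and the rule for named genes were chosen before the data were examined. Lists were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated correlation, and tested by fry, adjusted over 420 tests in 15 contrasts. The p beside each list is the one with an estimated correlation. Median, mean and test differed in sign for 2 lists that passed: ethylene in the V. longisporum cortex (median 0.11, mean -0.30, camera upward, p = 0.0255 with an estimated correlation) and sugar transport in the S. indica cortex (median -0.10, mean 0.14, camera upward, p = 0.393). Which lists to describe in single layers was chosen after the results were seen.

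Named genes were chosen by rule. In each of 12 layer comparisons they were the 4 highest and 4 lowest log2 fold changes among called genes whose infected libraries all lay above or all below the mock libraries. They were also up to 4 members of each list described with the smallest p, the 4 promoter genes and up to 3 markers per layer, the 5 genes with the smallest p for a difference between layers, up to 10 of the genes called the same way in the 3 mean responses, and the 3 genes with the smallest p higher in each microbe of a pair. Genes of the organelle genomes were left out, except as members of lists.

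Alternatives chosen with the design were RLE size factors, no filter on low counts, DESeq2 1.42.0, fits on the libraries of a layer alone, counts rebuilt from TPM, leaving out each library, binomial thinning of all libraries to the smallest total of the fit, removal of organelle genes, a replicate block, and for lists an estimated correlation and fry. After the library table and the spread between replicates were seen, a covariate for the level of photosynthetic markers in S. indica, fits without the 3 libraries in which AT2G01021 took over 5% of reads, fits on protein-coding genes alone and limma-voom with library quality weights were added. For other splits of the samples the infected and mock labels were exchanged within layers, and for mock layers the layer labels within experiments, with a fixed seed, 40 within an experiment, 30 over the 56 libraries and all 10 of the 3 against 3 designs, fewer than 100 because each needs a full refit. Replicates were compared by a chi-square over genes with at least 20 summed counts (1.9 to 25.6 per gene in all pairs) and by the correlation of log2 CPM with a prior count of 2.

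The edgeR code was tested on simulated counts in which 200 genes per layer changed, 100 by 2-fold and 100 by 4-fold. The share recovered was 0 to 1% and 6 to 10% for V. longisporum, 17 to 37% and 63 to 82% for P. parasitica, and 56 to 66% and 87 to 94% for S. indica, with 0 in the wrong direction. False calls were 18 to 40%, 8 to 20% and 4 to 7% of 10 to 15, 88 to 149 and 153 to 162 calls per layer, above the 5% threshold in every layer of the first 2 experiments. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.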

Results

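Polysome-bound RNA was profiled in 4 root cell layers of Arabidopsis thaliana seedlings that had been inoculated with 1 of 3 microbes or with a mock solution. Layers were separated by translating ribosome affinity purification (TRAP), in which a FLAG-tagged ribosomal protein, RPL18, is expressed from a layer-specific promoter and pulled down together with the RNA bound to its ribosomes. The promoters were those of GL2 for the rhizodermis, PEP for the cortex, SCR for the endodermis and SHR for the stele. Verticillium longisporum, a fungal pathogen of the vasculature of crucifers, was sampled 2 days after inoculation, and Phytophthora parasitica, a soil-borne oomycete pathogen, 2.5 h after it. No time is given in the labels for Serendipita indica, a root-colonising fungus known as a beneficial endophyte. Each microbe had its own mock libraries. The V. longisporum experiment held 17 libraries, with 2 per group and 3 in the infected stele. The P. parasitica experiment held 16 libraries, 2 per group, and the S. indica experiment held 23, with 3 per group and 2 in the infected rhizodermis. The comparisons asked which genes responded to each microbe in each layer, and whether responses differed between layers and between microbes. The labels do not say whether replicates came from separate cultures of plants, so p-values measure only the spread between these samples, which may be technical.

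Total estimated reads per library differed most in the V. longisporum experiment. Infected libraries there held 566454 to 1871947 reads and mock libraries 4089138 to 17839139. Totals were 3969647 to 14659022 in P. parasitica infected libraries and 706052 to 11769794 in their mocks, where the lowest was endodermis mock replicate 2. S. indica infected libraries held 3993569 to 14753327 and mock libraries 4432861 to 8563222. Genes with at least 1 read numbered 15914 to 20491 in V. longisporum infected libraries and 21301 to 22418 in their mocks. The gene AT2G01021 took 0.552 to 20.6% of reads in V. longisporum infected libraries against 0.0197 to 0.149% in the mocks. Chloroplast-encoded genes took 0.192 to 1.31% against 0.0245 to 0.0955%, and mitochondrial genes 0.151 to 1.64% against 0.0083 to 0.0404%. Replicates correlated across genes with Pearson's r of 0.552 to 0.644 in V. longisporum infected groups, compared with 0.948 to 0.981 in their mocks, 0.882 to 0.990 in the P. parasitica experiment and 0.954 to 0.988 in the S. indica experiment. Genes are not independent replicates in such a correlation. No pair of replicates agreed within sampling noise, so every library counted as 1 sample.

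**Figure D1:**
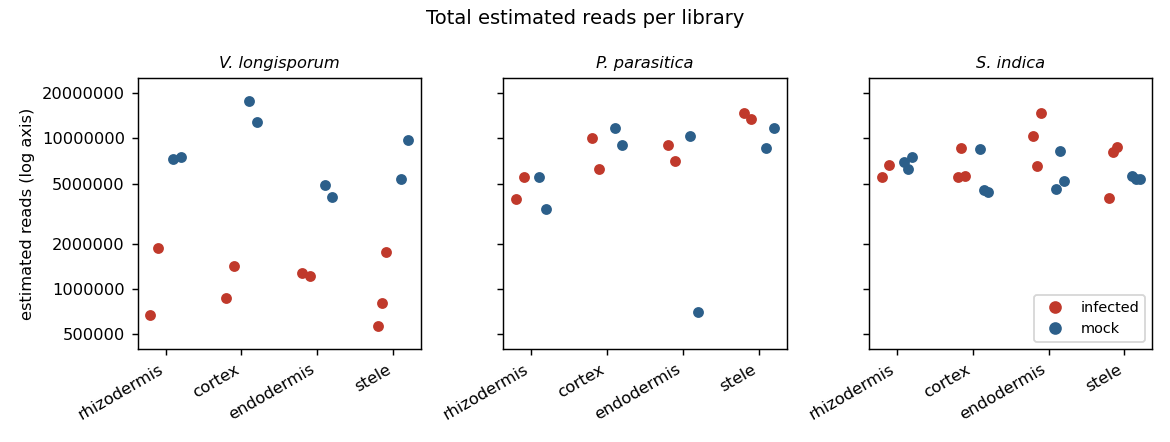
Total estimated reads per library, on a log axis, by layer and microbe, with 1 point per library and infected and mock libraries in separate colours. V. longisporum infected libraries lie between 566454 and 1871947 reads, below all of their mock libraries.

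The layer identity of the mock libraries was examined first, as a check of the labels. In mock libraries of the 3 experiments together, the gene whose promoter drove the tag was higher in its own layer than in the other 3 in each case. The log2 difference was 2.06 ± 0.19 (SE) for GL2 (AT1G79840), a regulator of root hair patterning, and 3.63 ± 0.18 for PEP (AT1G09750). It was 2.77 ± 0.11 for SCR (AT3G54220) and 0.95 ± 0.11 for SHR (AT4G37650), transcription factors that pattern the ground tissue. Each layer was represented by 7 mock libraries and its contrast by 21. Of the marker lists, 11 of 11 rhizodermis markers, 6 of 6 cortex markers, 13 of 13 endodermis markers and 9 of 11 stele markers were higher in their layer, and these counts were the same adjusted over the list alone. Root hair genes led the rhizodermis list, with PRP3 (AT3G62680) at 1.46 ± 0.13, LRX1 (AT1G12040) at 1.54 ± 0.14 and EXPA7 (AT1G12560) at 1.35 ± 0.14. Among cortex markers FLA13 (AT5G44130) stood at 3.32 ± 0.19, AT1G62510 at 3.29 ± 0.24 and C/VIF2 (AT5G64620) at 1.70 ± 0.18. Casparian strip genes led the endodermis list, where CASP2 (AT3G11550) stood at 3.89 ± 0.14, CASP4 (AT5G06200) at 3.78 ± 0.17 and the receptor kinase gene SGN3 (AT4G20140) at 2.90 ± 0.12. The stele was led by TMO5 (AT3G25710) at 2.25 ± 0.12, PHB (AT2G34710) at 2.30 ± 0.12 and the phosphate exporter gene PHO1 (AT3G23430) at 1.06 ± 0.09. The contrast called 7244 genes for the rhizodermis, 10280 for the cortex, 6241 for the endodermis and 6939 for the stele of 25264 tested. With RLE size factors in place of TMM, the share of calls that were higher moved from 50.4 to 75.2% in the rhizodermis and from 53.5 to 40% in the cortex, and the median over all genes from 0.02 to 0.18 and from -0.04 to -0.17. Leaving out P. parasitica endodermis mock replicate 1 lowered the endodermis count to 3156.

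The experiments differed in how far their layers stood apart. V. longisporum mock libraries had 6 of 11 rhizodermis, 4 of 6 cortex, 12 of 13 endodermis and 8 of 10 stele markers higher in their own layer (8, 4, 12 and 8 adjusted over the list alone). The infected libraries of that experiment had 0, 0, 4 and 0 of them (0, 0, 5 and 0 adjusted over the list alone). PEP, the cortex driver, stood at 222 and 223 CPM in the V. longisporum mock cortex libraries and at a mean of 14.9 to 28.6 in the other mock layers, but at a mean of 215 to 347 in the 4 infected layers. GL2 went from a mean of 39.4 CPM in mock rhizodermis and 0.885, 3.64 and 10.2 in the other layers to 28.6 and 6.93, 17.3 and 0 in infected ones. Mock and infected log2 contrasts were 2.93 ± 0.27 and 1.02 ± 0.44 for SCR, 1.27 ± 0.33 and 1.11 ± 0.59 for SHR. GL2 had 3.46 ± 0.46 and 4.11 ± 1.35. P. parasitica libraries had 10, 6, 12 and 9 own-layer markers higher in mock and 8, 5, 11 and 8 in infected libraries, out of 11, 6, 12 and 11, with the same counts adjusted over the list alone. Their median contrast was 1.67, 5.62, 4.94 and 1.82 log2 in mock and 2.03, 4.56, 5.05 and 1.37 in infected libraries. In the S. indica experiment 5, 1, 12 and 0 markers were higher in their layer in mock libraries (7, 1, 12 and 4 adjusted over the list alone) and 1, 3, 12 and 5 in infected ones (1, 3, 12 and 7), out of 11, 6, 13 and 11. Photosynthetic shoot markers, summed over 10 genes, reached 7627 to 32711 CPM in S. indica libraries, 618 to 1424 in V. longisporum infected, 93.4 to 1077 in V. longisporum mock and 59.2 to 3511 in P. parasitica libraries.

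**Figure D2:**
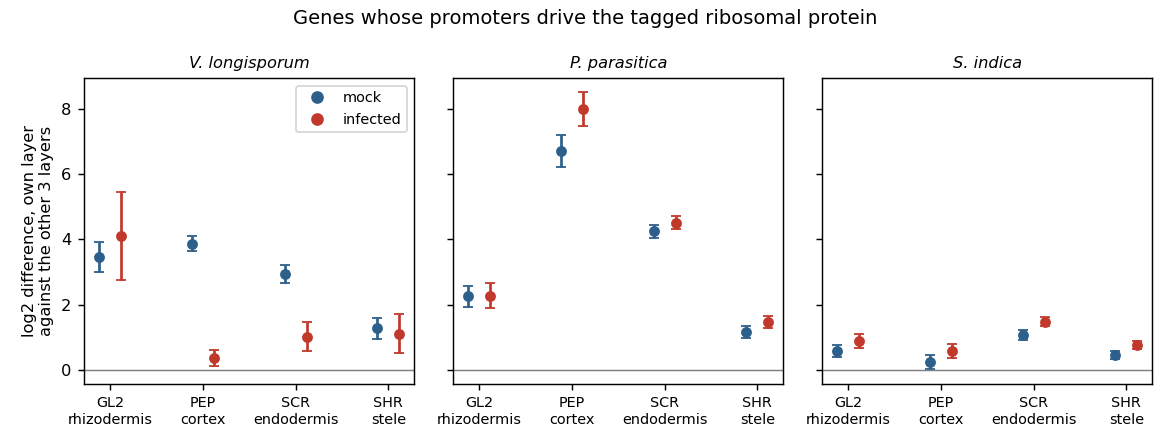
Log2 difference of GL2, PEP, SCR and SHR between the layer in which their promoter drove the tag and the other 3 layers, within each experiment, for mock and infected libraries in separate colours, with bars of 1 SE. With V. longisporum PEP stands at 3.86 ± 0.23 in mock and 0.36 ± 0.24 in infected libraries (0.25 ± 0.22 and 0.58 ± 0.22 with S. indica), and the infected GL2 value rests on a stele group with 0 reads.

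Roots inoculated with V. longisporum had higher levels of phosphate starvation, tryptophan-derived defence and hypoxia genes over the mean of the 4 layers (9 infected against 8 mock libraries). Of the phosphate starvation list 14 of the 16 measured members rose and 0 fell (15 and 1 adjusted over the list alone). Leading members were PS2 (AT1G73010, 4.41 ± 0.18), a phosphatase gene, IPS1 (AT3G09922, 4.82 ± 0.21), a non-coding RNA that mimics a microRNA target, SPX1 (AT5G20150, 3.2 ± 0.15), a phosphate sensor gene, and SQD2 (AT5G01220, 2.93 ± 0.14), of sulfolipid synthesis, given as log2 fold change ± SE here and below. In the tryptophan and camalexin list 14 of the 16 measured members rose and 1 fell (14 and 1 adjusted over the list alone), led by CYP71A12 (AT2G30750, 4.80 ± 0.17), FOX1 (AT1G26380, 4.5 ± 0.18), the glutathione transferase gene GSTF6 (AT1G02930, 4.12 ± 0.16) and the anthranilate synthase gene ASA1 (AT5G05730, 2.60 ± 0.16). All 13 hypoxia genes measured rose (13 adjusted over the list alone), with the alcohol dehydrogenase gene ADH1 (AT1G77120, 2.14 ± 0.13), sucrose synthase SUS4 (AT3G43190, 1.96 ± 0.12), pyruvate decarboxylase PDC1 (AT4G33070, 1.45 ± 0.13) and the regulator HRE2 (AT2G47520, 5.28 ± 0.36). Limma's camera test against all other genes, with an estimated correlation between list members, gave adjusted p = 0.00172 for phosphate starvation (median log2 fold change 2.98), 0.0061 for tryptophan and camalexin (median 2.48) and 0.0193 for hypoxia (median 1.45). A median in square brackets puts members whose group held 0 counts in any layer at their lower bound.

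Glucosinolate, immunity, jasmonate and ethylene lists rose as well. For indole glucosinolates, 13 of the 20 measured members rose and 3 fell (15 and 4 adjusted over the list alone), with the hydroxylase gene CYP81F2 (AT5G57220, 4.29 ± 0.16), the methyltransferase gene IGMT2 (AT1G21120, 4.07 ± 0.16), the regulator MYB51 (AT1G18570, 2.85 ± 0.23) and the transporter PEN3 (AT1G59870, 0.97 ± 0.10) (median log2 fold change 0.77, adjusted p = 0.0361 with an estimated correlation). For aliphatic glucosinolates, 13 of the 17 measured members rose and 0 fell (14 and 0 adjusted over the list alone), among them CYP83A1 (AT4G13770, 1.45 ± 0.17), BCAT4 (AT3G19710, 1.72 ± 0.21) and MAM1 (AT5G23010, 1.16 ± 0.18) of precursor and core synthesis (median log2 fold change 1.16, adjusted p = 0.0142 with an estimated correlation). In pattern-triggered immunity 15 of the 26 measured members rose and 1 fell (15 and 1 adjusted over the list alone), with the NADPH oxidase gene RBOHD (AT5G47910, 1.81 ± 0.13), the ubiquitin ligase gene PUB23 (AT2G35930, 1.73 ± 0.15) and WRKY40 (AT1G80840, 3.33 ± 0.33) (median log2 fold change 1.02 [1.18], adjusted p = 0.00217 with an estimated correlation). In the jasmonate list 12 of the 23 measured members rose and 0 fell (13 and 1 adjusted over the list alone), with the repressor genes JAZ1 (AT1G19180, 1.91 ± 0.15) and JAZ6 (AT1G72450, 1.94 ± 0.21) (median log2 fold change 1.72, adjusted p = 0.00708 with an estimated correlation). In the ethylene list 9 of the 18 measured members rose and 1 fell (9 and 2 adjusted over the list alone), with the chitinase gene PR3 (AT3G12500, 2.47 ± 0.12) and the synthesis gene ACS6 (AT4G11280, 2.28 ± 0.20) (median log2 fold change 0.93 [1.18], adjusted p = 0.00515 with an estimated correlation). Early touch and wound genes included TCH3 (AT2G41100, 2.68 ± 0.13) and ZAT10 (AT1G27730, 2.46 ± 0.16), with 5 of 10 higher (5 adjusted over the list alone; median log2 fold change 1.18 [1.80], adjusted p = 0.0231 with an estimated correlation). Photosynthetic shoot markers rose in 8 of 10 cases (8 adjusted over the list alone; median log2 fold change 2.35 [2.2], adjusted p = 0.0136 with an estimated correlation), with LHCB1.3 (AT1G29930, 2.68 ± 0.16) and LHCB2.1 (AT2G05100, 3.04 ± 0.20).

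The lists that follow had an adjusted p above 0.05 with an estimated correlation. Among endodermis markers 8 of the 13 measured members fell and 0 rose (9 and 0 adjusted over the list alone), with SGN1 (AT1G61590, -1.76 ± 0.26) and CASP1 (AT2G36100, -1.06 ± 0.19) (median log2 fold change -0.94, adjusted p = 0.291 with an estimated correlation). In the salicylic acid list 5 of the 16 measured members rose and 0 fell (5 and 1 adjusted over the list alone), with CBP60G (AT5G26920, 2.44 ± 0.32) and ICS1 (AT1G74710, 2.05 ± 0.28) (median log2 fold change 0.18 [0.28], adjusted p = 0.0781 with an estimated correlation). Among root triterpene genes 4 of the 7 measured members rose and 0 fell (4 and 0 adjusted over the list alone), with THAS1 (AT5G48010, 1.04 ± 0.16) (median log2 fold change 0.56, adjusted p = 0.0979 with an estimated correlation). In the nitrogen uptake and assimilation list 3 of the 10 measured members fell and 2 rose (5 and 2 adjusted over the list alone), with NIR1 (AT2G15620, -1.41 ± 0.12), NIA1 (AT1G77760, -1.25 ± 0.13) and the transporter NRT1.1 (AT1G12110, -0.99 ± 0.11) (median log2 fold change -0.38, adjusted p = 0.321 with an estimated correlation). In the phenylpropanoid and lignin list 9 of the 23 measured members fell and 3 rose (10 and 3 adjusted over the list alone), with CSE (AT1G52760, -0.96 ± 0.13) and CYP98A3 (AT2G40890, -1.0 ± 0.15) (median log2 fold change -0.43 [-0.39], adjusted p = 0.599 with an estimated correlation). The lists of auxin, abscisic acid, iron deficiency, sugar transport, suberin, xylem differentiation, flavonoid, heat shock and ER body genes, and the markers of rhizodermis, cortex, stele and root cap, had an adjusted p of 0.19 or more with an estimated correlation. In the cortex marker list the median was -1.14 [0.37], so its sign rests on the members at 0, and PEP itself rose (2.93 ± 0.17).

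The mean response called 7021 of 21743 genes, 2235 higher and 4786 lower, by edgeR's quasi-likelihood test. With RLE size factors the median log2 change over all genes moved from -0.34 to -0.08, and the higher share of calls from 31.8 to 51.1%, so that the excess of lower over higher calls depended on the scaling. Depth, the AT2G01021 share and, outside the cortex, the photosynthetic markers moved with infection in this experiment, as given above.

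Single layers of the V. longisporum experiment added to this. In the rhizodermis (2 libraries each) 12 of 26 immunity genes rose (15 adjusted over the list alone; median log2 fold change 1.53, adjusted p = 0.00344 with an estimated correlation), with RBOHD (2.14 ± 0.27) and PUB23 (2.19 ± 0.30). In the cortex (2 each) 12 of 17 aliphatic glucosinolate genes rose (15 adjusted over the list alone; median log2 fold change 2.35, adjusted p = 0.00485 with an estimated correlation), with CYP83A1 (3.00 ± 0.36) and IMD1 (AT5G14200, 2.35 ± 0.29). Nitrogen genes fell there in 5 of 10 cases (6 adjusted over the list alone; median log2 fold change -1.37, adjusted p = 0.00864 with an estimated correlation), with NIA1 (-3.30 ± 0.28), NRT1.1 (-2.76 ± 0.24) and NIR1 (-2.70 ± 0.26). In the endodermis (2 each) 11 of 13 endodermis markers fell (12 adjusted over the list alone; median log2 fold change -2.77, adjusted p = 0.0255 with an estimated correlation), with PER64 (AT5G42180, -3.16 ± 0.39), CASP1 (-2.79 ± 0.35) and SGN3 (AT4G20140, -2.77 ± 0.40) of the Casparian strip. Suberin genes fell in 13 of 20 cases there (13 adjusted over the list alone; median log2 fold change -1.83, adjusted p = 0.0375 with an estimated correlation), with ASFT (AT5G41040, -2.61 ± 0.34), GPAT5 (AT3G11430, -3.35 ± 0.46) and CYP86B1 (AT5G23190, -4.17 ± 0.57). In the stele (3 infected, 2 mock) 6 of 15 xylem differentiation genes fell (8 adjusted over the list alone; median log2 fold change -2.70 [-2.54], adjusted p = 0.0145 with an estimated correlation), with the secondary wall cellulose synthase genes CESA4 (AT5G44030, -3.73 ± 0.47) and CESA8 (AT4G18780, -2.79 ± 0.44) and the protease gene XCP1 (AT4G35350, -2.54 ± 0.35). Photosynthetic markers rose in 8 of 10 cases in the stele (9 adjusted over the list alone; median log2 fold change 3.90, adjusted p = 0.0119 with an estimated correlation). Those in the cortex, endodermis and stele moved with the lower layer contrast of the infected libraries: across the genes specific to a layer in P. parasitica mock libraries, own-layer genes changed by a median of -0.42 ± 0.06 in the cortex, -0.88 ± 0.09 in the endodermis and -0.63 ± 0.05 in the stele relative to all genes, and genes of other layers by 0.67 ± 0.06, 0.62 ± 0.04 and 0.44 ± 0.04. In the cortex the median log2 fold change was 1.42 for rhizodermis markers, 1.37 for stele markers and 1.5 for suberin genes, with adjusted p of 0.0855, 0.0436 and 0.0674 with an estimated correlation.

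The strongest changes of single genes involved groups with no reads, so folds are bounds for counting error alone, not replicate spread. In the endodermis CYP71A13 (AT2G30770), which acts with CYP71A12 in indole metabolism, reached 93.4 ± 64.5 CPM (SD, n = 2) against 0 reads in mock, at least 279-fold higher with a floor of 3 counts over the group. In the cortex the lipase gene GLIP1 (AT5G40990) was at least 153-fold higher and LBD22 (AT3G13850) at least 203-fold higher. In the rhizodermis AT5G11140 was at least 105-fold higher and the galactosidase gene BGAL11 (AT4G35010) at least 72.1-fold higher, while AT4G40020 stood at 65.5 ± 27.5 CPM against 1 read in mock. The genes AT1G09150 and UGLYAH (AT4G17050), of purine breakdown, were at least 45.5-fold and 44.5-fold lower in the infected rhizodermis. AT3G23160 was at least 69.7-fold lower in the endodermis and AT3G03560 at least 32.5-fold lower in the cortex. In the stele the 4 highest were pseudogenes, among them AT2G07697 and AT2G07784, which can share reads with near-identical copies, and AT1G05310 was at least 27.5-fold lower. AT5G11140, BGAL11 and UGLYAH lost their calls without rhizodermis infected 2, and LBD22 without cortex infected 2.

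Calls numbered 2099 in the rhizodermis (980 higher, 1119 lower), 3541 in the cortex (1487 and 2054), 4217 in the endodermis (2077 and 2140) and 3189 in the stele (1885 and 1304). With RLE size factors the higher share moved from 46.7 to 58.4% in the rhizodermis, from 42 to 66.9% in the cortex, from 49.3 to 67.1% in the endodermis and from 59.1 to 75.5% in the stele, and the median over all genes moved from -0.23 to 0 in the cortex and from 0 to 0.32 in the endodermis. Leaving out single libraries lowered the rhizodermis count to 731 (infected 2), 1007 (mock 1) and 985 (mock 2), the cortex count to 2297 (infected 2), 1673 (mock 1) and 1982 (mock 2), the endodermis count to 1976 (mock 1) and 2189 (mock 2), and the stele count to 1733 (infected 3), 1624 (mock 1) and 986 (mock 2).

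The response to V. longisporum differed between layers for 1694 genes by an F-test on the 4 layer effects. The gene with the smallest p was EXT3 (AT1G21310), a cell wall extensin gene, which rose by 1.69 ± 0.16 in the rhizodermis, 2.33 ± 0.17 in the endodermis and 1.86 ± 0.15 in the stele and fell in the cortex (-1.20 ± 0.16; F = 95.9, adjusted p = 1.46e-11). AT2G43150 rose by 1.80 ± 0.18 in the stele and 1.24 ± 0.19 in the rhizodermis and fell in the cortex (-1.45 ± 0.19; adjusted p = 5.57e-09). WAT1 (AT1G75500), a vacuolar auxin transporter gene, rose in the cortex (1.75 ± 0.28) and fell in the stele (-2.15 ± 0.24; adjusted p = 1.61e-07) and rhizodermis (-1.15 ± 0.28, a call lost without rhizodermis infected 2 or mock 2). AT5G07030 rose in the cortex (3.17 ± 0.30; adjusted p of the difference 1.61e-07) and endodermis (1.16 ± 0.28, a call lost without endodermis infected 2 or mock 1) and fell in the stele (-1.05 ± 0.25, a call lost without stele mock 2). AT4G30170 fell in the cortex (-2.08 ± 0.22; adjusted p of the difference 1.98e-07) and rose in the endodermis (0.99 ± 0.21, a call lost without endodermis mock 2) and stele (0.67 ± 0.20, a call lost without stele infected 2 or either mock). For these 5 genes the mean of the infected group differed less between layers than that of the mock group, as for EXT3, at 3882 to 5352 CPM in infected and 670 to 9647 in mock layers. Photosynthetic markers differed in 9 of 10 cases (10 adjusted over the list alone), phenylpropanoid genes in 14 of 23 (16), suberin genes in 10 of 20 (13) and aliphatic glucosinolate genes in 8 of 17 (11), while 0 of 23 jasmonate and 0 of 8 heat shock genes differed (0 each adjusted over the list alone). The count fell to 1057 without stele mock 2, 835 and 1011 without cortex mock 1 or 2, and 1112 and 1127 without rhizodermis mock 1 or 2. It was 301 with limma-voom, 583 after thinning and 2826 without the libraries in which AT2G01021 took over 5% of reads.

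Roots sampled 2.5 h after P. parasitica had higher levels of immunity, tryptophan, indole glucosinolate and ethylene genes over the mean of the 4 layers (8 infected against 8 mock libraries). All 26 pattern-triggered immunity genes measured rose (26 adjusted over the list alone), led by NHL10 (AT2G35980, 4.83 ± 0.16), the kinase gene MPK11 (AT1G01560, 5.43 ± 0.22), WRKY29 (AT4G23550, 3.98 ± 0.15) and the ubiquitin ligase gene PUB24 (AT3G11840, 2.96 ± 0.11) (median log2 fold change 2.89, adjusted p = 0.0193 with an estimated correlation). All 15 tryptophan and camalexin genes rose (15 adjusted over the list alone), with FOX1 (7.90 ± 0.17), CYP71A12 (6.79 ± 0.15) and the camalexin gene PAD3 (AT3G26830, 5.97 ± 0.15) (median log2 fold change 3.81 [3.57], adjusted p = 0.00492 with an estimated correlation). In the indole glucosinolate list 16 of the 20 measured members rose and 2 fell (16 and 2 adjusted over the list alone), with CYP81F2 (7.17 ± 0.17), the regulators MYB122 (AT1G74080, 5.99 ± 0.14) and MYB51 (5.16 ± 0.14) and the transporter PEN3 (3.82 ± 0.11) (median log2 fold change 2.13, adjusted p = 0.0183 with an estimated correlation). In the ethylene list 17 of the 18 measured members rose and 0 fell (18 and 0 adjusted over the list alone), with ACS6 (3.1 ± 0.12), ERF6 (AT4G17490, 4.43 ± 0.17) and ERF1 (AT3G23240, 3.58 ± 0.19) (median log2 fold change 1.70, adjusted p = 0.0238 with an estimated correlation). All 13 hypoxia genes rose (13 adjusted over the list alone), with the haemoglobin gene PGB1 (AT2G16060, 2.36 ± 0.12) and SUS1 (AT5G20830, 2.1 ± 0.11), although adjusted p was 0.0561 with an estimated correlation. In the salicylic acid list 14 of the 18 measured members rose and 1 fell (14 and 1 adjusted over the list alone), with the regulators CBP60G (4.05 ± 0.13) and SARD1 (AT1G73805, 4.09 ± 0.15) (median log2 fold change 1.74 [1.5], adjusted p = 0.0946 with an estimated correlation). In the jasmonate list 15 of the 23 measured members rose and 1 fell (16 and 1 adjusted over the list alone), with JAZ1 (2.43 ± 0.12) higher and VSP1 (AT5G24780, -1.78 ± 0.11) lower (median log2 fold change 0.77 [0.56], adjusted p = 0.148 with an estimated correlation).

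Phosphate starvation and root triterpene lists fell, and other lists changed for part of their members. All 16 phosphate starvation genes were lower (16 adjusted over the list alone), with SQD2 (-2.97 ± 0.10), the galactolipid synthase genes MGD3 (AT2G11810, -2.11 ± 0.10) and MGD2 (AT5G20410, -2.03 ± 0.13), and SPX3 (AT2G45130, -2.28 ± 0.12) (median log2 fold change -1.36, adjusted p = 0.0145 with an estimated correlation). Among root triterpene genes 6 of the 7 measured members fell and 0 rose (6 and 0 adjusted over the list alone), with the thalianol cluster genes THAS1 (-4.49 ± 0.16), THAD (AT5G47990, -4.10 ± 0.15) and THAH (AT5G48000, -2.94 ± 0.15) (median log2 fold change -2.94, adjusted p = 0.0139 with an estimated correlation). In the aliphatic glucosinolate list 15 of the 17 measured members fell and 1 rose (15 and 1 adjusted over the list alone), with the regulator MYB28 (AT5G61420, -1.66 ± 0.14) lower and the sulfotransferase gene SOT17 (AT1G18590, 1.52 ± 0.12) higher (median log2 fold change -0.99, adjusted p = 0.377 with an estimated correlation). Among ER body genes 6 of the 8 measured members fell and 1 rose (6 and 1 adjusted over the list alone), with PBP1 (AT3G16420, -1.65 ± 0.11), NAI1 (AT2G22770, -1.53 ± 0.12) and MEB1 (AT4G27860, -1.35 ± 0.11) (median log2 fold change -1.27, adjusted p = 0.211 with an estimated correlation). In the phenylpropanoid and lignin list 12 of the 23 measured members rose and 5 fell (12 and 5 adjusted over the list alone), with CCR2 (AT1G80820, 4.32 ± 0.11), the ammonia lyase genes PAL2 (AT3G53260, 2.79 ± 0.10) and PAL1 (AT2G37040, 2.15 ± 0.10) and the regulator MYB15 (AT3G23250, 4.69 ± 0.17) (median log2 fold change 0.43, adjusted p = 0.229 with an estimated correlation). Nitrogen genes rose in 6 of 11 cases and fell in 3 (6 and 3 adjusted over the list alone; median log2 fold change 0.49, adjusted p = 0.368 with an estimated correlation), with the nitrate reductase genes NIA2 (AT1G37130, 2.79 ± 0.10) and NIA1 (1.83 ± 0.10) higher. Heat shock genes rose in 6 of 8 cases (6 adjusted over the list alone; median log2 fold change 1.62, adjusted p = 0.2 with an estimated correlation), with HSP90.1 (AT5G52640, 2.42 ± 0.12). Touch genes included TCH3 (6.05 ± 0.15), with 7 of 12 higher and 3 lower (7 and 3 adjusted over the list alone; median log2 fold change 2.13, adjusted p = 0.162 with an estimated correlation).

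Remaining lists of the P. parasitica mean response had an adjusted p of 0.111 or more with an estimated correlation. Suberin genes were higher in 9 and lower in 8 of 21 cases (9 and 9 adjusted over the list alone), with GPAT7 (AT5G06090, 2.54 ± 0.15) higher and MYB92 (AT5G10280, -0.93 ± 0.14) lower. Of auxin genes 4 were higher and 2 lower of 12, of abscisic acid genes 4 and 4 of 13, of sugar transport genes 5 and 1 of 8, of flavonoid genes 4 and 1 of 10 and of iron genes 2 and 3 of 11 (4 and 2, 5 and 4, 5 and 1, 4 and 1, 2 and 2 adjusted over the list alone). The iron median was -0.37. Stele markers fell in 7 and rose in 1 of 11 cases (7 and 1 adjusted over the list alone; median -0.69), with AHK4 (AT2G01830, -1.13 ± 0.10) and PHB (AT2G34710, -0.94 ± 0.13), and endodermis markers fell in 5 of 12 (5 adjusted over the list alone; median -0.34). The mean response called 10519 of 20836 genes, 4932 higher and 5587 lower.

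In single layers P. parasitica calls numbered 6093 in the rhizodermis (3120 higher, 2973 lower), 5640 in the cortex (3108 and 2532), 5438 in the endodermis (3297 and 2141) and 6526 in the stele (3365 and 3161), with 2 libraries per group. CYP82C2 (AT4G31970), a cytochrome P450 gene of indole metabolism, stood at 325 ± 42.9 CPM (SD, n = 2) in the infected rhizodermis against 0 reads in mock, at least 966-fold higher with a floor of 3 counts over the group. In the cortex it rose by 11.76 ± 0.43 and AT5G48430 by 10.12 ± 0.29. The dirigent gene DIR5 (AT1G64160) was at least 814-fold higher in the rhizodermis and AT5G22520 at least 186-fold in the endodermis. In the stele the peroxidase gene PRXCA (AT3G49110) was at least 325-fold higher, WRKY30 (AT5G24110) at least 226-fold and the kinase gene WAKL10 (AT1G79680) at least 190-fold. Lower bounds applied to the falls too, with the wax gene CER4 (AT4G33790) at least 34.1-fold lower in the rhizodermis, BBX31 (AT3G21890) at least 22.9-fold lower in the cortex and the nicotianamine synthase gene NAS1 (AT5G04950) at least 41.1-fold lower in the stele. Phenylpropanoid genes rose in 12 and fell in 2 of 23 cases in the rhizodermis (12 and 4 adjusted over the list alone; median log2 fold change 0.83, adjusted p = 0.148 with an estimated correlation), with CCR2 (4.93 ± 0.23), PAL2 (3.5 ± 0.21) and MYB15 (4.19 ± 0.32). ER body genes fell in 7 of 8 cases in the cortex (7 adjusted over the list alone; median log2 fold change -1.98, adjusted p = 0.062 with an estimated correlation), with PBP1 (-2.54 ± 0.22) and NAI1 (-2.72 ± 0.25). Touch genes rose in 7 of 12 cases in the endodermis and 0 fell (7 and 1 adjusted over the list alone; median log2 fold change 2.92, adjusted p = 0.0859 with an estimated correlation), with TCH3 (6.80 ± 0.34) and ERF13 (AT2G44840, 5.81 ± 0.51). Ethylene genes rose in 14 of 18 cases in the stele (17 adjusted over the list alone; median log2 fold change 2.62, adjusted p = 0.0145 with an estimated correlation), with ACS2 (AT1G01480, 5.71 ± 0.32) and ERF6 (5.39 ± 0.34), and sugar transport genes in 5 of 8 (5 adjusted over the list alone; median log2 fold change 1.06, adjusted p = 0.05 with an estimated correlation), with ERD6 (AT1G08930, 5.71 ± 0.26) and STP13 (AT5G26340, 6.05 ± 0.32). Leaving out single libraries lowered the stele count to 4153 (infected 1), 4283 (infected 2) and 4166 (mock 2), and the endodermis count to 3412 (infected 2) and 2267 (mock 1).

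**Figure D3:**
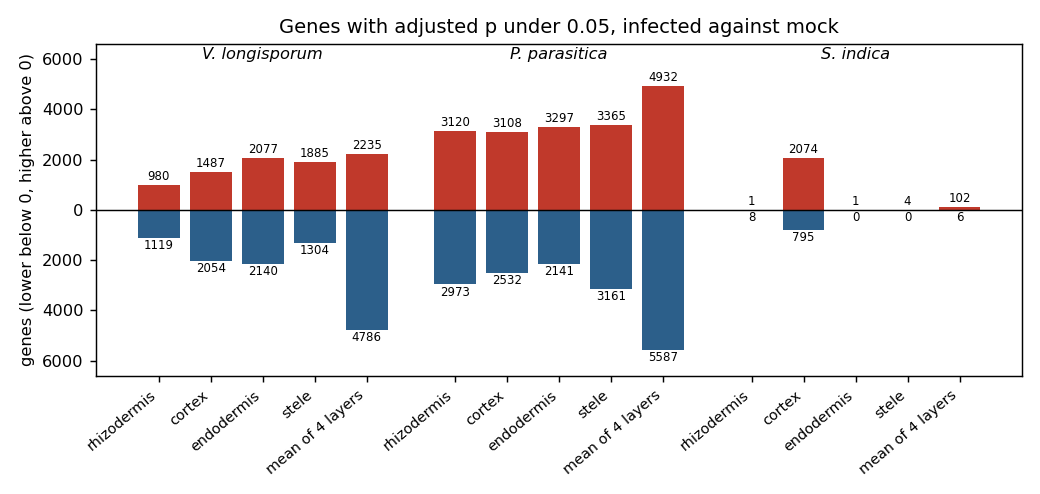
Number of genes called in each layer and in the mean of the 4 layers, infected against mock, with higher genes above 0 and lower genes below. P. parasitica calls range from 5438 to 6526 per layer, V. longisporum calls from 2099 to 4217, and of the S. indica layers the cortex has 2869 and the others 1 to 9.

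The response to P. parasitica differed between layers for 2247 genes. Polyol transporter genes were among the 5 with the smallest p: PMT6 (AT4G36670) rose by 6.60 ± 0.33 in the stele, 3.33 ± 0.31 in the rhizodermis and 3.15 ± 0.52 in the endodermis (a call lost without endodermis mock 1), with 0.01 ± 0.23 in the cortex (adjusted p = 2.92e-09), and PMT5 (AT3G18830) rose by 4.86 ± 0.23 in the stele, 2.01 ± 0.21 in the rhizodermis, 1.62 ± 0.21 in the endodermis and 0.68 ± 0.20 in the cortex (the last a call lost without cortex mock 2; adjusted p = 1.2e-08). DIN10 (AT5G20250), a sugar-starvation gene, rose by 4.44 ± 0.29 in the endodermis and 4.17 ± 0.26 in the stele, with 0.33 ± 0.23 and 0.20 ± 0.22 in the outer layers (adjusted p = 3.17e-09). The laccase gene LAC1 (AT1G18140) rose by 6.24 ± 0.27 in the stele, 3.99 ± 0.29 in the rhizodermis, 2.07 ± 0.37 in the cortex and 0.70 ± 0.26 in the endodermis (the last a call lost without any 1 endodermis or stele library, either cortex mock or either rhizodermis infected library; adjusted p = 4.57e-09), and the lipoxygenase gene LOX1 (AT1G55020) by 5.40 ± 0.23 in the cortex, 2.76 ± 0.21 in the rhizodermis, 2.16 ± 0.20 in the endodermis and 1.86 ± 0.20 in the stele (adjusted p = 3.67e-08). Of the lists, 15 of 26 immunity genes differed between layers (19 adjusted over the list alone), as did 14 of 20 indole glucosinolate genes (16), 7 of 8 ER body genes (7) and 11 of 23 jasmonate genes (17), but 0 of 11 rhizodermis and 0 of 6 cortex markers (0 each). Genes called in all 4 layers numbered 1588 higher and 585 lower. The count of differing genes fell to 1157 and 1213 without stele infected 1 or 2, 1338 and 1259 without stele mock 1 or 2, 1408 and 1229 without endodermis infected 1 or 2, and 1346 without cortex infected 2. It was 996 after thinning and 3958 with limma-voom.

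With S. indica, the cortex was the layer with many calls. Tryptophan-derived defence genes led there (3 infected against 3 mock libraries): 14 of 15 genes of the tryptophan and camalexin list rose (14 adjusted over the list alone; median log2 fold change 1.16, adjusted p = 8.57e-06 with an estimated correlation), with FOX1 (3.92 ± 0.24), GSTF6 (3.08 ± 0.19), WRKY33 (AT2G38470, 1.37 ± 0.13) and the tryptophan synthase gene TSA1 (AT3G54640, 1.1 ± 0.09). Immunity genes rose in 15 of 26 cases (18 adjusted over the list alone; median log2 fold change 0.77, adjusted p = 0.000858 with an estimated correlation), with WRKY53 (AT4G23810, 2.1 ± 0.24), PUB23 (1.06 ± 0.13), MPK3 (AT3G45640, 0.85 ± 0.13) and the chitin receptor gene CERK1 (AT3G21630, 0.77 ± 0.12). Salicylic acid genes rose in 14 of 17 cases (15 adjusted over the list alone; median log2 fold change 0.96, adjusted p = 0.0193 with an estimated correlation), with CBP60G (1.62 ± 0.27) and FMO1 (AT1G19250, 1.72 ± 0.29). Nitrogen genes rose in 6 of 9 cases (6 adjusted over the list alone; median log2 fold change 0.57, adjusted p = 0.163 with an estimated correlation), with the ammonium transporter gene AMT1;3 (AT3G24300, 0.99 ± 0.16) and the nitrate transport gene NRT3.1 (AT5G50200, 1.15 ± 0.22). Endodermis markers fell in 4 of 13 cases (8 adjusted over the list alone; median log2 fold change -0.95, adjusted p = 0.356 with an estimated correlation), with ESB1 (AT2G28670, -1.06 ± 0.31) and MYB36 (AT5G57620, -1.04 ± 0.32). Stele markers fell in 4 of 11 cases (7 adjusted over the list alone; median log2 fold change -0.55, adjusted p = 0.184 with an estimated correlation), with SHR (AT4G37650, -0.55 ± 0.17) and SUC2 (AT1G22710, -0.74 ± 0.23), and photosynthetic markers in 4 of 10 (10 adjusted over the list alone; median log2 fold change -1.07, adjusted p = 0.305 with an estimated correlation), with LHCB2.1 (-1.11 ± 0.35). These 5 marker genes lost their calls without cortex mock 2, mock 3, infected 2 or infected 3, SHR also without infected 1, and LHCB2.1 also without endodermis infected 3, rhizodermis infected 1 or rhizodermis infected 2. Single genes at the extremes were AT1G26410 (5.08 ± 0.44) and, among lower ones, CIB1 (AT4G34530), at 0.0594 ± 0.103 CPM (1 read) against 8.10 ± 6.11 in mock (SD, n = 3).

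Cortex calls numbered 2869 of 19977 genes, 2074 higher and 795 lower. Genes specific to the cortex in P. parasitica mock libraries stood 0.42 ± 0.02 higher in the infected cortex relative to all genes and those of other layers changed by -0.24 ± 0.01, and summed photosynthetic markers were 7627 to 11616 CPM in infected and 12381 to 26591 in mock cortex libraries. With the photosynthetic marker level as a covariate, added after the data were seen, the cortex count was 598. Leaving out single libraries gave 1368 (cortex infected 2), 1287 (infected 3), 5282 (mock 1), 1239 (mock 2) and 1006 (mock 3).

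The number of calls in the other S. indica layers depended on the fit. In the rhizodermis (2 infected, 3 mock libraries) 9 genes were called, 1 higher and 8 lower, with IGMT2 higher (1.78 ± 0.29) and the ferric reductase gene FRO2 (AT1G01580) lower (-2.03 ± 0.31), as were AT3G59320 (-1.98 ± 0.30) and CYP78A8 (AT1G01190) (-1.21 ± 0.18). The iron deficiency list as a whole had 1 of 17 members lower and 0 higher (4 and 1 adjusted over the list alone; median log2 fold change 0.04, adjusted p = 0.21 with an estimated correlation). In the endodermis (3 each) the 1 gene called was FOX1, higher by 2.4 ± 0.37. In the stele (3 each) the 4 genes called were PXMT1 (AT1G66700), a methyltransferase gene (2.29 ± 0.32), FOX1 (1.90 ± 0.30), WRKY53 (1.64 ± 0.27) and the transporter gene UMAMIT29 (AT4G01430) (1.31 ± 0.23). At an unadjusted p under 0.05, edgeR gave 2594 genes in the rhizodermis, 1403 in the endodermis and 1460 in the stele, and DESeq2 called 123, 5 and 7 with adjustment, limma-voom 135, 1 and 875. On the layer's libraries alone edgeR called 1210 genes in the rhizodermis, 7 of them among the 9, and 0 in the endodermis and the stele, where 704 and 1376 had an unadjusted p under 0.05. Summed photosynthetic markers were 29643 to 32711 CPM in infected and 20538 to 24475 in mock rhizodermis libraries. Rhizodermis markers stood at a mean log2(CPM + 1) of 3.2 to 3.22 in the infected and 3.72 to 3.92 in the mock ones, with 0 of 11 called lower by edgeR (4 adjusted over the list alone; median log2 fold change -0.63, adjusted p = 0.00648 with an estimated correlation). Genes specific to the rhizodermis in P. parasitica mock libraries changed there by a median of -0.27 ± 0.02 relative to all genes, and genes of other layers by 0.08 ± 0.01. Without either rhizodermis infected library the rhizodermis count was 0 and the genes named for it lost their calls, IGMT2 also without rhizodermis mock 1. That count was 22 and 38 without stele infected 1 or 2, 17, 61 and 20 without stele mock 1, 2 or 3, 66 without endodermis infected 1, 68 and 37 without endodermis mock 2 or 3, 49 and 15 without cortex mock 1 or 3, and 80 without rhizodermis mock 2 or 3. The endodermis count was 0 without infected 1, infected 3 or mock 1 and 4 without mock 2, all of which cost FOX1 its call, and 3, 2 and 2 without stele infected 1, stele infected 2 or cortex mock 3. The stele count was 0 without infected 2, which cost the 4 genes their calls, and 9, 1, 2 and 1 without infected 1, infected 3, mock 1 or mock 3. FOX1, WRKY53 and UMAMIT29 also lost theirs without infected 3 or mock 3, FOX1 and WRKY53 without mock 2, and WRKY53 and UMAMIT29 without mock 1.

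Over the mean of the 4 layers (11 infected against 12 mock libraries) S. indica calls numbered 108, of which 102 were higher. Tryptophan and camalexin genes rose in 9 of 15 cases (13 adjusted over the list alone; median log2 fold change 0.35, adjusted p = 8.57e-06 with an estimated correlation), with FOX1 (2.49 ± 0.16), GSTF6 (1.25 ± 0.10) and CYP71A12 (1.59 ± 0.17). Indole glucosinolate genes rose in 4 of 20 (10 adjusted over the list alone; median log2 fold change 0.17, adjusted p = 0.000294 with an estimated correlation), with IGMT2 (2.09 ± 0.13), CYP81F2 (1.44 ± 0.11) and MYB51 (0.55 ± 0.09). Immunity genes rose in 2 of 26 (9 adjusted over the list alone; median log2 fold change 0.22, adjusted p = 0.00177 with an estimated correlation), ethylene genes in 2 of 20 (4 adjusted over the list alone; median log2 fold change 0.06, adjusted p = 0.0153 with an estimated correlation) and touch genes in 2 of 9 (5 adjusted over the list alone; median log2 fold change 0.29, adjusted p = 0.0193 with an estimated correlation). The other 23 lists had an adjusted p above 0.05 with an estimated correlation, among them hypoxia (p = 0.148, with ADH1 (0.35 ± 0.06)), salicylic acid (p = 0.15), phosphate starvation (p = 0.951, median -0.02) and photosynthetic markers (p = 0.315, median -0.36). The count was 1096 without cortex mock 1, and 63, 71, 71, 70, 70 and 62 without stele infected 2, stele infected 3, stele mock 3, cortex infected 3, rhizodermis infected 2 or rhizodermis mock 1.

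The response to S. indica differed between layers for 747 genes, and the 5 with the smallest p were all highest in the cortex. CYP81F2 rose there by 3.71 ± 0.22 against 0.47 to 1.01 in the other layers (adjusted p = 1.74e-05). GSTF6 rose by 3.08 ± 0.19 against 0.37 to 0.83 (adjusted p = 3.43e-05) and GSTF7 (AT1G02920) by 3.09 ± 0.21 against 0.30 to 0.79 (adjusted p = 1.02e-04). YLS5 (AT2G38860) rose by 1.26 ± 0.10 (adjusted p = 7.57e-05) and TSA1 by 1.1 ± 0.09 (adjusted p = 1.45e-04). Differing genes made up 12 of 15 in the tryptophan and camalexin list (13 adjusted over the list alone), 9 of 20 in the indole glucosinolate list (14), 5 of 17 in the iron deficiency list (8) and 4 of 9 in the nitrogen list (7). The count was 3302 without cortex mock 1, 1349 without endodermis mock 2, 1171 without stele infected 1 and 1147 without stele mock 2. It was 93 and 203 without cortex mock 2 or 3, 118 and 100 without cortex infected 2 or 3, 204 and 294 without rhizodermis infected 1 or 2, 315, 496 and 427 without rhizodermis mock 1, 2 or 3, 335 and 327 without stele infected 2 or 3, 402 and 386 without stele mock 1 or 3, and 470 without endodermis infected 3. With the marker covariate it was 328, with DESeq2 1981 and with limma-voom 7378.

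**Figure D4:**
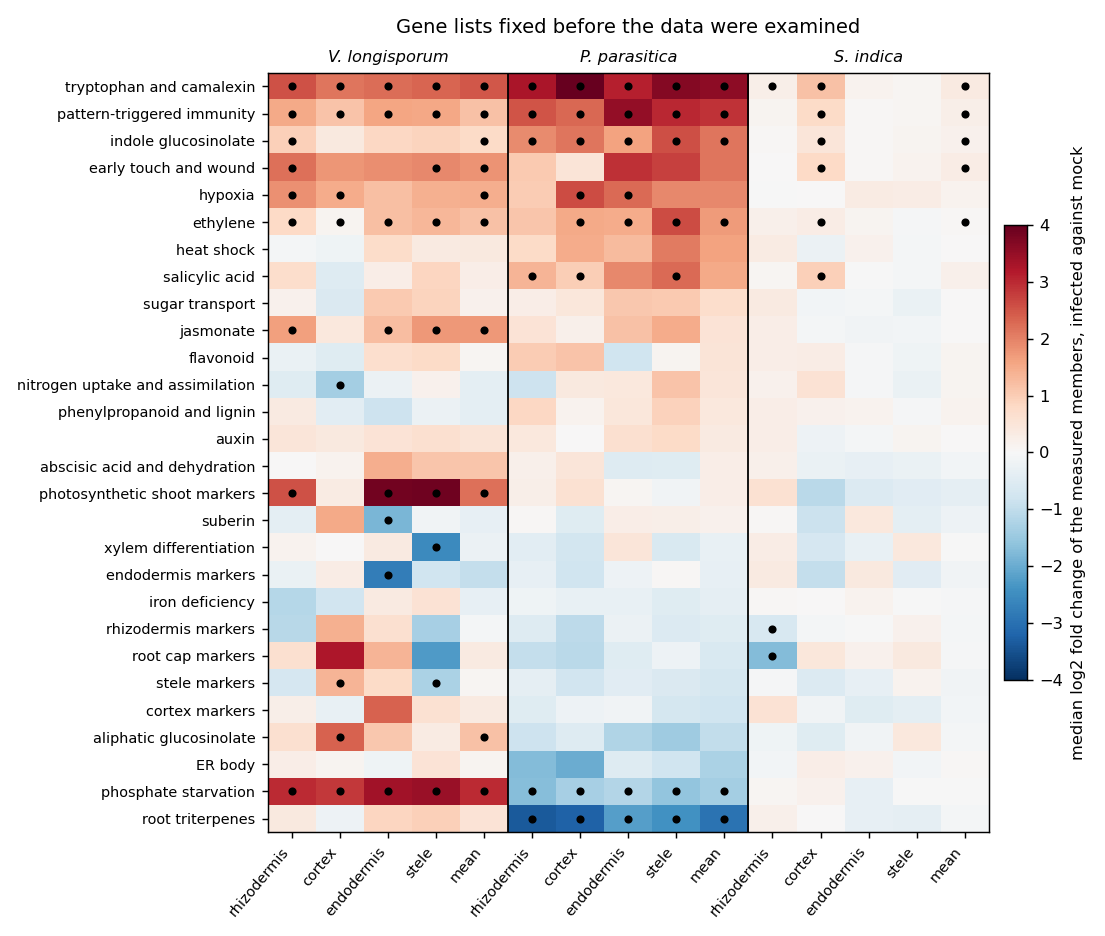
Median log2 fold change of the measured members of each gene list, infected against mock, for each layer and the mean of the 4 layers of each experiment. Members of a group at 0 counts are at their lower bound, colours saturate at 4 in both directions and dots mark an adjusted p under 0.05 by camera with an estimated correlation. Phosphate starvation genes are higher in the V. longisporum mean (2.98) and lower in the P. parasitica mean (-1.36).

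Mean responses were then compared between microbes in 1 fit over the 56 libraries, where each response was relative to its own mock and the microbe cannot be told apart from the time point and the experiment. Phosphate starvation genes separated V. longisporum from P. parasitica, with 16 of 16 members higher for V. longisporum (16 adjusted over the list alone, median difference 4.48). The phosphatase gene PEPC1 (AT1G17710) differed by 7.00 ± 0.17, SQD2 by 5.90 ± 0.16 and the phosphodiesterase gene SRG3 (AT3G02040) by 4.06 ± 0.11. Aliphatic glucosinolate genes were higher for V. longisporum in 14 of 18 cases (15 adjusted over the list alone) and ER body genes in 7 of 8 (7), while 19 of 26 immunity genes (20), 14 of 20 indole glucosinolate genes (15) and 14 of 16 tryptophan and camalexin genes (14) were higher for P. parasitica. SAG21 (AT4G02380), a late embryogenesis-type gene, PAL2 and DIN10 differed by -3.90 ± 0.13, -3.15 ± 0.12 and -3.36 ± 0.15. The level of phosphate starvation genes in mock libraries differed between experiments: the group means of their log2(CPM + 1) were 3.24 to 3.84 in V. longisporum mocks, 7.12 to 7.67 in P. parasitica mocks and 3.18 to 3.61 in S. indica groups, and they were 5.83 to 6.22 in V. longisporum infected and 5.50 to 5.76 in P. parasitica infected groups. In all, 9447 of 25264 genes differed between these 2 responses. RLE size factors moved the share higher for V. longisporum from 24.2 to 40.9% and the median difference over all genes from -0.37 to -0.05.

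**Figure D5:**
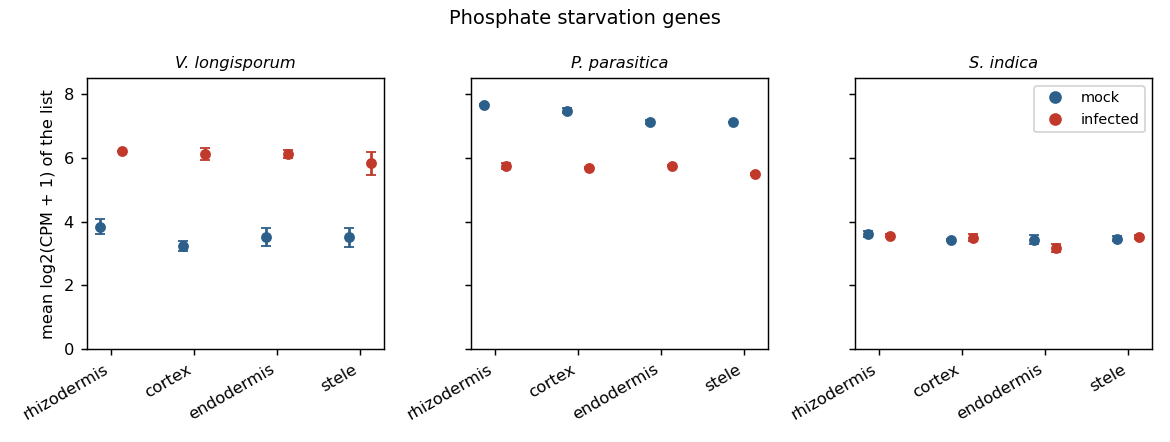
Mean log2(CPM + 1) over the phosphate starvation list by layer for each experiment, with points for the mean and bars for 1 SD over the 2 or 3 libraries of a group, and infected and mock groups in separate colours. V. longisporum infected groups lie at 5.83 to 6.22 against 3.24 to 3.84 in mock.

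Against S. indica, V. longisporum had higher responses of phosphate starvation genes (15 of 16, and 15 adjusted over the list alone), tryptophan and camalexin genes (14 of 16, 14), hypoxia genes (11 of 13, 12), jasmonate genes (13 of 23, 13) and photosynthetic markers (8 of 10, 8), and lower ones of endodermis markers (8 of 13, 8). SRG3 differed by 2.94 ± 0.11, G3Pp1 (AT3G47420), a glycerol-3-phosphate permease gene, by 3.12 ± 0.13 and AT2G36950 by 3.19 ± 0.14. GRP2B (AT2G21060), DYL1 (AT1G28330) and the aquaporin gene PIP1B (AT2G45960) differed by -2.30 ± 0.14, -2.33 ± 0.15 and -1.74 ± 0.11. The 2 responses differed for 9312 genes, of which 26% were higher for V. longisporum with TMM and 45.4% with RLE size factors. P. parasitica against S. indica had higher responses of immunity genes (23 of 26, and 25 adjusted over the list alone), tryptophan and camalexin genes (14 of 16, 14), hypoxia genes (13 of 13, 13), ethylene genes (16 of 20, 16) and heat shock genes (5 of 8, 5), and lower ones of phosphate starvation (14 of 16, 14), aliphatic glucosinolate (13 of 18, 15) and triterpene genes (5 of 7, 5). The calmodulin-like gene TCH3 differed by 5.58 ± 0.16, AT5G35735 by 4.19 ± 0.12 and AT4G20830 by 4.04 ± 0.12, while MLP329 (AT2G01530), SQD2 and THAS1 differed by -3.59 ± 0.16, -3.13 ± 0.15 and -4.36 ± 0.20. These responses differed for 6712 genes.

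Genes called in all 3 mean responses were examined last. Of 18611 genes tested in all 3 experiments, 84 were higher in each, where 2.47 would be shared by independent lists, and 0 were lower in each, where 0.44 would be. For V. longisporum, P. parasitica and S. indica, log2 fold changes of named genes were as follows. FOX1 had 4.5 ± 0.18, 7.90 ± 0.17 and 2.49 ± 0.16, and IGMT2 4.07 ± 0.16, 6.12 ± 0.26 and 2.09 ± 0.13. CYP81F2 had 4.29 ± 0.16, 7.17 ± 0.17 and 1.44 ± 0.11, and GSTF6 4.12 ± 0.16, 6.46 ± 0.17 and 1.25 ± 0.10. The others named were PXMT1, GSTF7, CYP71A12, AT2G15220, AT1G26250 and the transcription factor gene NAC042 (AT2G43000), with 0.87 ± 0.11 to 1.87 ± 0.18 for S. indica. Fisher's exact test, one-sided, took genes as independent. V. longisporum and P. parasitica shared 931 higher genes (475 expected, adjusted p = 6.69e-125) and 1509 lower genes (1348 expected, adjusted p = 2.81e-09). Opposite calls numbered 1030 and 451 (1167 and 549 expected). P. parasitica and S. indica shared 101 higher genes (24.1 expected, adjusted p = 2.81e-62). In the cortex, with 1006 to 5282 S. indica calls without 1 library, they shared 874 (311 expected, adjusted p = 2.43e-226). The 84 and the 101 rest on the S. indica mean, which had 62 to 1096 calls without 1 library, and 2 of 40 splits, the real one included, gave as many calls and shared as many (highest other 128 and 373). Across genes, which are not independent replicates, the mean responses correlated with Pearson's r of 0.302 and Spearman's rho of 0.153 for V. longisporum and P. parasitica, 0.012 and -0.002 for V. longisporum and S. indica, and 0.29 and 0.208 for P. parasitica and S. indica.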

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

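The tests of library scaling for the phosphate list, of the photosynthetic marker covariate and of what splits share were chosen after those results were seen. Results stand here because the effect differed between groups by a test of the difference itself. Responses differed between layers for 1694 genes with V. longisporum, 2247 with P. parasitica and 747 with S. indica. Mean responses differed for 9447 genes between V. longisporum and P. parasitica, 9312 between V. longisporum and S. indica and 6712 between P. parasitica and S. indica. F for a difference between layers was 95.9 for EXT3, 59.1 for AT2G43150, 43.6 for WAT1, 43.2 for AT5G07030 and 41.7 for AT4G30170 with V. longisporum. It was 85.7 for PMT6, 89.0 for DIN10, 82.1 for LAC1, 73.2 for PMT5 and 64.7 for LOX1 with P. parasitica, and 48.5 for CYP81F2, 44.6 for GSTF6, 32.9 for YLS5, 41.0 for GSTF7 and 29.1 for TSA1 with S. indica. Log2 differences of mean responses, V. longisporum minus P. parasitica, were 7.00 for PEPC1, 5.90 for SQD2, 4.06 for SRG3, -3.90 for SAG21, -3.15 for PAL2 and -3.36 for DIN10. For V. longisporum minus S. indica they were 2.94 for SRG3, 3.12 for G3Pp1, 3.19 for AT2G36950, -2.30 for GRP2B, -2.33 for DYL1 and -1.74 for PIP1B. For P. parasitica minus S. indica they were 5.58 for TCH3, 4.19 for AT5G35735, 4.04 for AT4G20830, -3.59 for MLP329, -3.13 for SQD2 and -4.36 for THAS1.

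V. longisporum infected libraries differed less between layers than their mock libraries, though not clearly for the drivers SHR and GL2, as given above. With all libraries thinned to the 566454 reads of the smallest, the marker contrast in mock still exceeded that in infected libraries by a median of 1.69 ± 0.268 log2, with 1.44, 1.35, 2.16 and 1.93 from rhizodermis to stele, which argues against depth. RNA of other layers in each infected pull-down is a candidate explanation. Own-layer genes fell while other-layer genes rose in 3 of 4 layers. The rhizodermis was the exception (0.14 and 0.05), though its markers had a median of -1.92 [-1.1]. The higher mitochondrial share given above goes with unspecific RNA in infected pull-downs. A response to infection that evens out the layers stays open, untested.

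The S. indica cortex held 2869 calls against 1 to 9 in the other layers, a contrast that depended on the fit: the layer's libraries alone gave 1868 against 1210 in the rhizodermis, and limma-voom 7673 against 875 in the stele and 135 in the rhizodermis. With the photosynthetic marker covariate its count was 598, against 30, 0 and 2 elsewhere, which argues against shoot-like RNA as the whole cause. Genes called higher had a median cortex contrast of 1.05 ± 0.031 log2 in P. parasitica mocks, genes called lower -0.55 ± 0.074 (all genes 0.03). RNA of other layers in mock cortex libraries is a candidate explanation, though rhizodermis markers were 3.2 ± 0.03 in infected and mock cortex. Own-layer genes rose also in endodermis (0.16) and stele (0.22), with 1 and 4 calls, not rhizodermis (-0.27). A cortex response stays open, untested.

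Phosphate starvation genes rose with V. longisporum and fell with P. parasitica. With V. longisporum the list median was 3.25 with RLE size factors and 2.98 with TMM, and with P. parasitica it lay -1.29 ± 0.2 from the median of all genes, which scaling would move alike. Both argue against scaling. Mixing of layers is argued against by the lowest V. longisporum infected library lying 1.42 above the highest mock library of any layer, and the highest P. parasitica infected library -1.27 from the lowest mock library, in mean log2(CPM + 1). The list's group means in mock differed between experiments, 3.24 to 3.84 against 7.12 to 7.67. The biological explanation was not tested.

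Of 40 splits, the real one included, 1 gave as many calls as the real one for the V. longisporum mean (7021, highest other 175). The P. parasitica mean also gave 1 of 40 (10519, highest other 5710). This lowest possible share argues against chance labels, not culture differences. Microbe pairs gave 1 of 30 each: 9447 against a highest other of 4696, 9312 against 5350 and 6712 against 1345. The mock layers gave 1 of 30 each as well, with 7244 against 2919, 10280 against 1874, 6241 against 2898 and 6939 against 3642. Chance cannot be excluded for the S. indica mean (108, 2 of 40, highest other 2168). The split with 2168 calls points to a structure of the samples: it kept the labels of the 6 cortex libraries, exchanged those of the rhizodermis, and its groups differed most in photosynthetic marker level (0.632 log2, 0.402 in the real split; 77 calls with the covariate), though the next 4 in that level, 0.475 to 0.565, had 0 to 9 calls among genes also tested with P. parasitica. It shared 373 of 791 higher genes with P. parasitica (47%), the real split 101 of 102 (99%), and 2 smaller splits, which kept 19 and 18 of 23 labels, 38 of 38 and 26 of 27. For differences between layers the splits decide nothing, because exchanging the infected and mock labels of a whole layer turns its response around and so itself makes layers differ. They gave as many genes in 4 of 40 with V. longisporum (1694, highest other 4990), 2 of 40 with P. parasitica (2247, 4164) and 2 of 40 with S. indica (747, 2044). The 10 splits of 3 against 3 are too few for a share under 0.05: the S. indica cortex had 2869 (1 of 10, highest other 0), the endodermis 1 (2 of 10, 627) and the stele 4 (2 of 10, 541).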

How the results depend on the processing

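The photosynthetic marker covariate, the fits without libraries rich in AT2G01021, protein-coding genes alone and limma-voom with library weights were chosen after the data were seen. Counts stayed within 1.5 times of those reported with RLE size factors, counts rebuilt from TPM, organelle genes removed and protein-coding genes alone. Without the low-count filter the S. indica rhizodermis gave 26. Fits on the libraries of a layer alone gave 1555 for the V. longisporum cortex, 3628 and 9868 for the P. parasitica rhizodermis and stele, and 1210, 1868, 0 and 0 for S. indica from rhizodermis to stele. Thinning gave 1022, 1301, 1892 and 1321 for V. longisporum layers, 3997 for their mean and 583 for differences, and 3417, 2880, 3427 and 3196 for P. parasitica layers, 6116 for their mean and 996 for differences. It gave 0 for the S. indica endodermis and 1 for the stele, 4988, 4765 and 2985 for V. longisporum against P. parasitica, V. longisporum against S. indica and P. parasitica against S. indica, and 2696, 4741, 3070 and 2911 for mock layers, so depth limits how many genes can be called. The covariate gave 30, 598, 0 and 2 for S. indica layers and 328 for differences. Without the libraries rich in AT2G01021, 2826 genes differed between V. longisporum layers. DESeq2 gave 2117 for the V. longisporum stele, and 123, 5 and 7 for the S. indica rhizodermis, endodermis and stele, 222 for the mean and 1981 for differences. Limma-voom gave 1395, 1751 and 1912 for the V. longisporum rhizodermis, cortex and endodermis and 301 for differences, 3815 and 10472 for the P. parasitica rhizodermis and stele and 3958 for differences, and 135, 7673 and 875 for the S. indica rhizodermis, cortex and stele, 2126 for the mean and 7378 for differences. Camera passed 92 list tests with an estimated correlation against 204 with the preset one. The cause of these shifts was not tested, apart from depth in the thinned libraries.

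With the file-name number as a replicate block the V. longisporum stele gave 1445, and the other 24 counts stayed within 1.5 times. Same-numbered libraries did not deviate together (median correlation of 0, -0.006 and -0.011), so the numbers were not used to pair samples.

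Without 1 library at a time, V. longisporum counts ranged from 731 to 2727 in the rhizodermis, 1673 to 4454 in the cortex, 1976 to 4885 in the endodermis and 986 to 4180 in the stele, 5902 to 7462 for the mean and 835 to 2525 for differences. P. parasitica counts ranged from 4488 to 6357 in the rhizodermis, 3816 to 6104 in the cortex, 2267 to 5914 in the endodermis and 4153 to 7099 in the stele, 7597 to 10565 for the mean and 1157 to 2852 for differences. S. indica counts ranged from 0 to 80 in the rhizodermis, 1006 to 5282 in the cortex, 0 to 4 in the endodermis and 0 to 9 in the stele, 62 to 1096 for the mean and 93 to 3302 for differences. Between microbes the ranges were 8259 to 9984 for V. longisporum against P. parasitica, 8324 to 9752 for V. longisporum against S. indica and 4951 to 7306 for P. parasitica against S. indica, and for mock layers 5631 to 7712, 8714 to 10834, 3156 to 6634 and 5245 to 7339 from rhizodermis to stele. Where a layer is left with 1 library in a group, that library is assumed to vary like the others.

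Of the named genes' results, 12 changed direction or fell to 0, and the cause was not tested. Log2 fold changes were then 0.64 for PER64 in the P. parasitica cortex after thinning, and 0.59 for AT1G62510, 0.06 for RBCS1A and 0.05 for LHCB2.1 in the S. indica cortex with the covariate. In the V. longisporum mean without the libraries rich in AT2G01021 it was -0.04 for DFR. Over single libraries left out, values ranged from -6.36 to 0.78 for TT7 in the P. parasitica endodermis and -1.38 to 0.57 for BRN1 in its mean, the highest without endodermis mock 1. In the V. longisporum cortex they ranged from -0.19 to 2.03 for CASP1, -0.40 to 3.02 for GPAT5 and -4.34 to 4.82 for HSP18.2, the lowest without infected 2. For FEZ and COR15A, with 0 mock reads, fitted values from 0 to 9.89 and 0 to 8.70 are not measured folds. Leaving out 1 library ended 35 of 78, 48 of 107, 29 of 100 and 34 of 97 calls of named genes in V. longisporum layers and 19 of 106 for the mean, 14 of 101, 24 of 113, 32 of 105, 14 of 104 and 11 of 110 with P. parasitica, and 4 of 4, 32 of 83, 1 of 1, 4 of 4 and 7 of 23 with S. indica.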

Other observations

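With V. longisporum 355 genes were called higher and 99 lower in all 4 layers. Genes called in both directions in different layers numbered 274 with V. longisporum and 266 with P. parasitica. Genes called in 1 layer alone that also passed the test of a difference between layers numbered 66, 407, 171 and 87 with V. longisporum from rhizodermis to stele, 88, 145, 95 and 149 with P. parasitica, and 8, 620, 0 and 1 with S. indica. For the 0 in the S. indica endodermis, where edgeR called 1 gene in all, 1403 genes had an unadjusted p under 0.05 and DESeq2 called 5, limma-voom 1.

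Cortex responses to V. longisporum and S. indica were compared over 18784 genes tested in both. Of the 2054 genes called lower with V. longisporum, 712 were called higher with S. indica and 23 lower, where independent lists would share 225.5 and 82.3. Of the 1261 called higher with V. longisporum, 163 were called higher with S. indica and 131 lower, where independent lists would share 138 and 50.6. Layer contrast moved with this. Cortex-specific genes of P. parasitica mock libraries had median cortex changes of -0.42 with V. longisporum and 0.42 with S. indica, relative to all genes.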
